A study of Zea mays with 2 samples.

How the data were processed

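ATAC-seq of B73 maize roots was analysed in 2 libraries of 1 group, named library 1 and library 2 after the replicate numbers in the labels. Per the labels' protocols, nuclei were purified by flow sorting before tagmentation and the libraries were amplified by PCR. Per the submitters' processing notes, Trimmomatic 0.33, Bowtie 1.1.1, SAMtools 1.3.1, Picard and MACS2 were used with genome build B73 RefGen_v4; their settings and order are not given in the sources used here. The deposited data hold 1 line per aligned read with its position and strand, and both mates of each pair. The deposited score column is 255 on every line and was not used to filter reads. Reads were 30 to 36 bases long, and no library held a pair of fragments with the same start and end, so that duplicates had been removed before deposit. A deposited description of columns names a peak summit and its height, which the read lists do not hold; the authors' peaks were not used here.

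Mates were joined by read name into fragments, and the 5 prime end of each read was taken as a cut. Plus and minus strand cuts overlapped most often by 9 bp, 3.17 and 3.02 times the median of the overlaps compared in libraries 1 and 2, as for reads that were not shifted for the Tn5 insertion, and cuts were used unshifted. A shift by 4 and 5 bp was an alternative. Depth was 26995950 and 24870448 reads. Of all fragments, 96.2% and 87.8% lay on chromosomes 1 to 10. With counts of this size the 95% Clopper-Pearson intervals of the shares of fragments are narrow (96.2% to 96.2%, and 87.8% to 87.9%); they cover counting error only.

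Accessible regions were called in each library from cuts in windows of 150 bp at steps of 50 bp. A one-sided Poisson test compared each window with the larger of the chromosome mean and the mean of the surrounding 10 kb. Windows with a Benjamini-Hochberg adjusted p under 0.01 and at least 4-fold enrichment in each library were kept, and those within 150 bp were merged. In simulated counts for chromosome 10, 200 regions of 300 bp were planted per fold. Of those at 4-fold 11.5% were recovered, 38.5% at 6-fold, 85.5% at 10-fold and 100% at 20-fold, with 0 false regions among 473 called. False regions were counted in simulated counts only, so that their share among the real regions was not measured. Real cuts favoured some sites, and whether this yields false regions was not tested. Planted folds of 4 equal the threshold required in each library, so that few pass. The binomial test recovered 198 of 200 simulated regions changed by 2-fold among 40000, with 9 false calls. Simulated regions had a mean of 300 fragments over both libraries. The median real region held fewer, so that recovery in most real regions was not measured.

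Region density was compared between the outer and the middle of 3 parts of equal length of each chromosome by a two-sided exact sign-flip test. Density ratios over all chromosomes are geometric means. Clustering was compared with 1000 random placements in 1 kb bins that held a cut, within the same 1 Mb blocks. Fragments per region, counted by their plus strand ends within it, were compared between libraries with an exact binomial test. Counts of fragments in bins with at least 20 fragments were compared by a Pearson chi-square given each bin's total. The chance number of fragments with the same ends was estimated by shifting positions by 400, 700 and 1000 bp, and by multiplying the result by the excess of single shared starts and of single shared ends. This estimate takes a mean preference for all positions, so that it is too low where sites differ in preference. For identical fragments, regions were widened by 500 bp on each side before fragments were placed inside or outside. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

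The tests and most alternatives were fixed before the data were examined. The plan counted the libraries as replicates. They were counted as 1 sample, a choice made after the data were seen. The reason was that outside regions library 1 shared more fragments with lane 1 of library 2 than estimated from mean cut site preference. Without the shared fragments the counts of both varied slightly beyond counting noise. All lanes were kept for the values reported. Short fragment enrichment, clustering, the comparison of regions between libraries and the lane comparisons were added after the data were seen. The regions named are the 10 with the largest fold, taking the lower of the libraries, at most 5 kb wide; the rule also required them to be distal to genes, which was not applied. A genome sequence and gene annotation of B73 RefGen_v4 were not used here. Distal shares, promoter and transcription start site accessibility, gene lists, named genes, motifs and GC content were therefore not analysed here, and 1 kb bins took the place of promoters in the comparison of libraries. Organelle and unplaced sequences were left out of the regions.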

Results

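Chromatin accessibility was profiled by ATAC-seq in roots of maize (Zea mays) inbred B73, the reference inbred line, at 6 days of age. In this assay the Tn5 transposase inserts sequencing adapters into DNA that is not covered by protein, so that the ends of each fragment mark accessible positions. There was 1 group with 2 libraries and no treatment, so that the data describe where accessible chromatin lies in root and how closely the libraries resemble each other. Library 1 held 13497975 fragments and library 2 held 12435224, which gave 25980108 and 21846180 cut positions on chromosomes 1 to 10. Library 1 and lane 1 of library 2 shared 10.6% of fragments of the latter, and with these included their counts differed by less than the sampling noise of independent counts. With identical fragments left out, the counts differed by slightly more than that noise. Whether they are separate libraries was left open, and they were counted as 1 sample. Values are given for each library or as their mean, with no SD, and without a biological replicate check.

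As called here, root chromatin was accessible in short, scattered regions that took up a small part of the chromosomes. A total of 48700 regions were found in both libraries, covering 22.8 Mb or 1.08% of the 2106 Mb of chromosomes 1 to 10 (B73 RefGen_v4). The median region was 450 bp wide, 5% were wider than 900 bp, and the widest spanned 2050 bp. Each window had to reach 4-fold over a 10 kb mean that includes it. Wide, evenly accessible stretches could therefore not pass, and the short widths follow in part from the calling. The length covered ran from 7929400 bp at 8-fold to 47415400 bp, in 64097 regions, with a background of 50 kb. These regions held 37.5% of nuclear cuts in library 1 and 37.6% in library 2, which was 34.6-fold their share of chromosome length. Against the 69.6% of 1 kb bins that held any cut, the excess was 24.1-fold. Regions were chosen from these same cuts as windows above expectation, so that an excess follows from the calling. Accessibility was unevenly spread among regions: the median was a depth-normalised cut count (CPM) of 4.26, and the 10% of regions with the most cuts held 39.9% of all cuts in regions. The share of cuts in regions moved with the calling threshold, from 51.6% at 2-fold to 19.8% at 8-fold enrichment, where 23825 regions were left. With 1 read per position and strand it was 26.8%.

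Folds compare a window with the larger of the chromosome mean and the mean of the 10 kb that includes it. With this background they reach 67 at most. Where the 10 kb mean is the larger, they measure the window's share of those cuts. Some folds below, as on chromosome 4 at 242659401 to 242659750, rest on the chromosome mean instead. The largest was on chromosome 1 at 62848851 to 62849250, with 198 cuts in library 1 and 145 in library 2, at 46.0-fold and 50.7-fold. The next were on chromosome 8 at 40987101 to 40987550 (42.4-fold and 39.1-fold), chromosome 4 at 242659401 to 242659750 (41.0-fold and 38.7-fold) and chromosome 4 at 72820951 to 72821450 (38.2-fold and 38.3-fold). A region on chromosome 2 at 98044101 to 98044700 reached 38.1-fold and 39.0-fold with 430 and 408 cuts. Another 3 of the 10 regions with the largest fold lay on chromosome 8, at 113337051 to 113337550, 169749951 to 169750400 and 88337551 to 88338050. The remaining members of this set were on chromosome 5 at 85860751 to 85861450 and chromosome 9 at 25862501 to 25863000. The accessibility of the 10 regions ranged from 2.85 to 17.6 CPM. The folds and their order depended on the background: with 50 kb, taking the lower of the libraries, the region on chromosome 1 had 53.3-fold, that on chromosome 2 141.5-fold and that on chromosome 9 5.37-fold. A wider background raises the largest fold possible, so that folds with 50 kb and with 10 kb are not on the same scale. With 1 read per position and strand the 10 folds were lower and their order also changed. They ran from 22.0 on chromosome 8 at 169749951 to 169750400 to 31.3 on chromosome 1.

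The regions with the most cuts were others. Chosen after their values were seen, the most cut region of each chromosome reached between 89.9 CPM on chromosome 6 and 169 CPM on chromosome 7. The latter lay at 169300001 to 169300950, with 4276 cuts in library 1 and 3801 in library 2, or 165 and 174 CPM. On chromosome 8, 147058751 to 147059650 had 151 CPM. On chromosome 10, 1982101 to 1982650 had 134 CPM and a fold of 34.4 and 34.7, which became 151.9 with a background of 50 kb and 33.9 with 1 read per position and strand. On chromosome 9, 115424151 to 115424800 had 93.9 CPM at 8.07-fold and 8.25-fold, with 3.97-fold, under the threshold of 4, with 1 read per position and strand and 33.5-fold with 50 kb. The widest region, also singled out after its values were seen, lay on chromosome 4 at 168571251 to 168573300 and had 46.8 CPM. Genes at or near these regions were not analysed here.

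Accessible regions were denser towards the chromosome ends. Each chromosome was divided into 3 parts of equal length. The outer parts held a mean of 26.2 ± 1.98 regions per Mb (SD over 10 chromosomes) and the middle parts 16.7 ± 2.90. The ratio was above 1 on 10 of 10 chromosomes, with a geometric mean of 1.59. Chromosome 2 had the steepest contrast at 2.15, followed by chromosome 5 at 1.94, whereas chromosome 6 (1.104) and chromosome 10 (1.14) were nearly even. The two-sided exact sign-flip test over the 10 chromosomes gave p = 0.00195, the smallest it can give. Chromosomes of this sample were the units of the test, so that it does not speak for other plants. The middle part is defined by length and does not follow the position of the centromere.

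**Figure D1:**
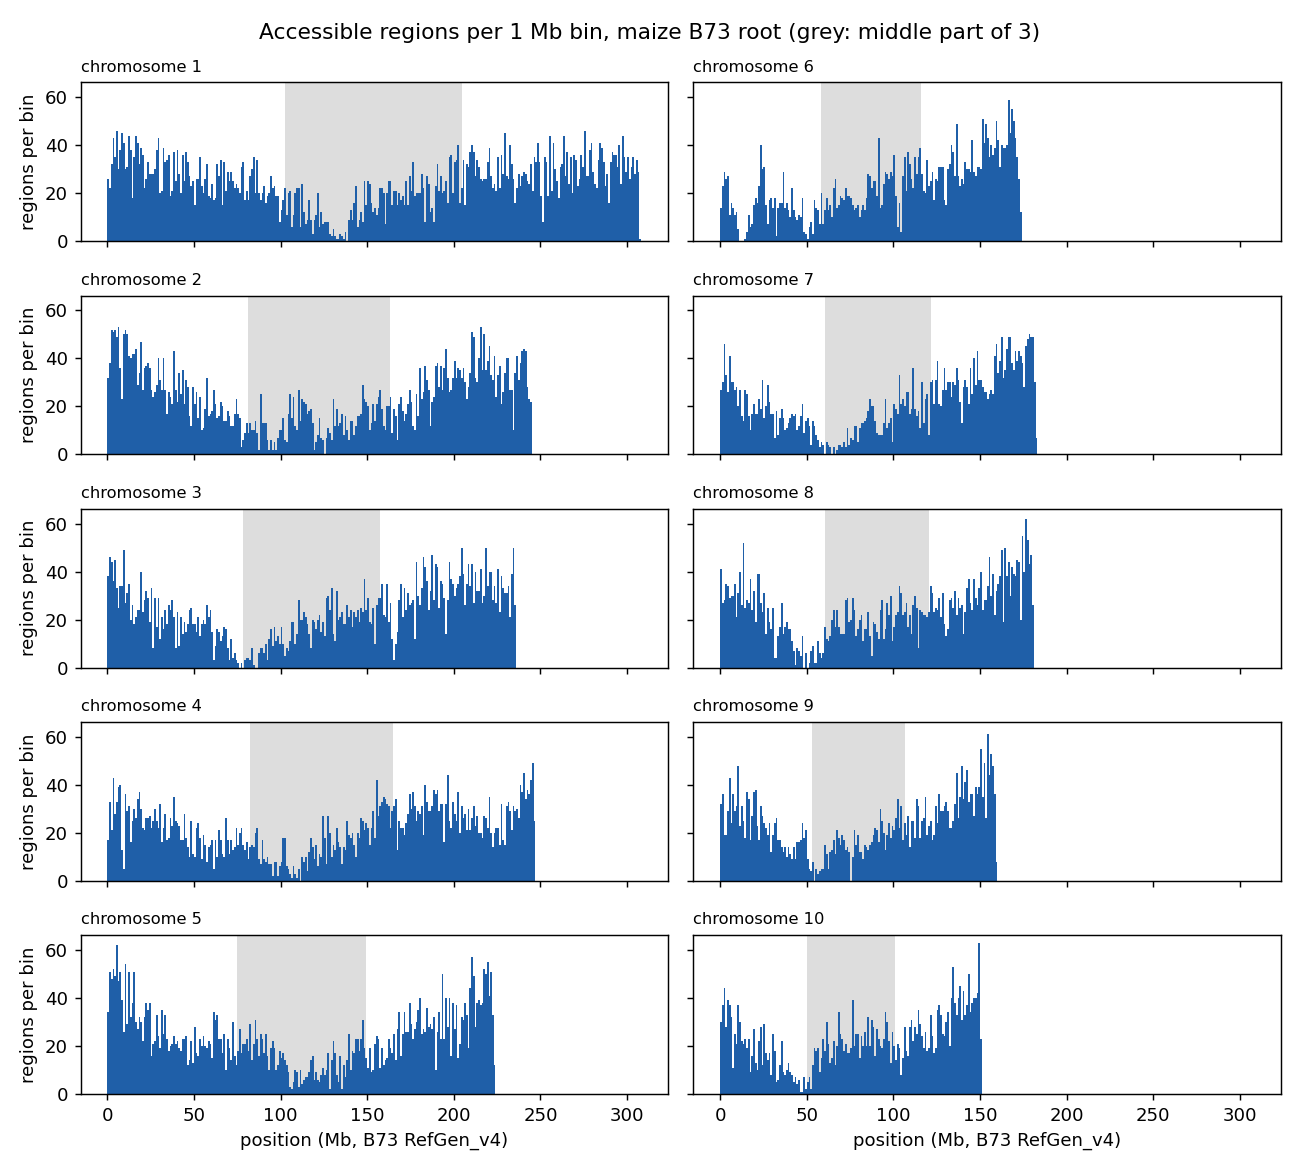
Number of accessible regions found in both libraries per 1 Mb bin (bars, y axis) along chromosomes 1 to 10 (x axis, Mb), with the middle part of each chromosome shaded grey. The densest bin, near the end of chromosome 10, holds 63 regions against a median of 22.

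The densest bins were close to chromosome ends. The 1 Mb bin at 149000001 to 150000000 on chromosome 10 held 63 regions, and bins at 5000001 to 6000000 on chromosome 5 and 176000001 to 177000000 on chromosome 8 held 62 each. The median bin held 22, and 17 of 2101 bins held none. The longest interval without a region was 4.21 Mb on chromosome 6, from 10071851 to 14282600, where 22.3% of 1 kb bins held a cut. On chromosome 3 an interval of 3.05 Mb from 84007751 to 87054950 was free of regions, with 41.7% of bins covered. The longest such interval of chromosome 4, 1.28 Mb from 8560101 to 9836000, had 69.8% of its bins covered, against 69.9% of the whole chromosome, but only 0.165 and 0.183 times the cuts per kb of the chromosome in libraries 1 and 2.

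Regions also lay near each other more often than by chance. A neighbour within 2 kb was found for 29.7% of regions, against a mean of 12.7% in 1000 random placements that kept the number of regions in each 1 Mb block, a ratio of 2.34 (two-sided permutation p = 0.001998, the smallest these placements can give). The ratio fell to 1.33 (permutation p = 0.001998) when regions within 500 bp were merged. Merged regions cannot lie under 500 bp apart, whereas random placements can, so that part of this fall follows from the merging. How much of the clustering lay under 500 bp was therefore not measured. Within 5 kb the shares were 42.2% and 26.8%. The median distance between neighbouring regions was 17.6 kb.

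Accessible regions were rich in short fragments. Fragments of up to 100 bp, which are too short to span a nucleosome, made up 24.0% of fragments inside regions and 15.7% outside in library 1, and 26.8% and 18.0% in library 2, a mean ratio of 1.51. Fragments of 180 to 250 bp, about the length protected by a nucleosome and its linker, were less frequent inside, at 20.3% against 25.6% in library 1 and 19.8% against 26.6% in library 2. Those of 320 to 470 bp were 0.541 times as frequent inside as outside. Fragments were assigned by their midpoint to regions called from cuts. A long fragment cut in a narrow region can have its midpoint outside, so that part of these ratios can follow from region width. Fragment lengths had a period of 10.4 bp inside regions and 10.5 bp outside, close to a turn of the DNA helix.

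**Figure D2:**
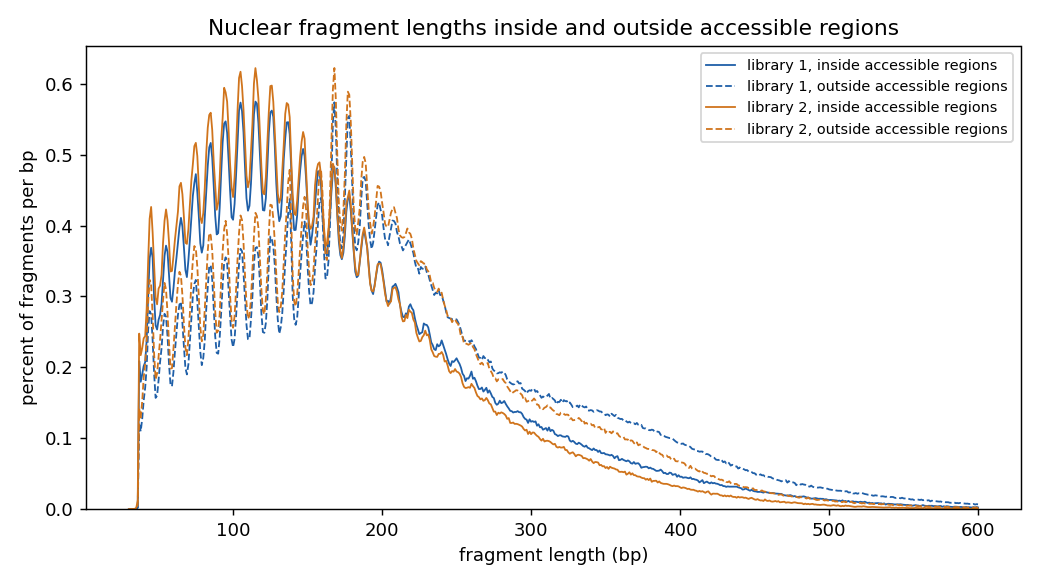
Percent of nuclear fragments at each length in bp, for each library inside (solid) and outside (dashed) accessible regions. Short fragments are more frequent inside, with a mean ratio of 1.51 for those of up to 100 bp.

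Around region summits, the midpoints of short fragments were 11.1-fold over the flanks in each library, and midpoints of fragments of 180 to 250 bp were 5.41-fold and 5.39-fold. At 200 bp from the summit the order was the other way round, with 2.27-fold for short fragments and 2.79-fold for the longer class in library 1. Summits were placed where cuts were most frequent, so that a maximum near the centre, and in part the wider profile of longer fragments, whose midpoints lie farther from a cut, follow from their definition.

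**Figure D3:**
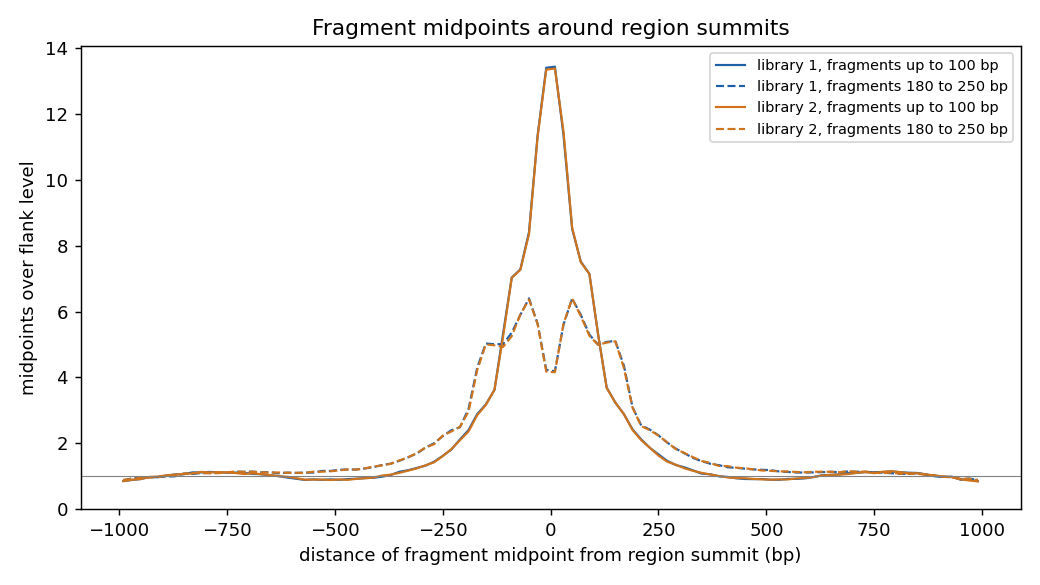
Fragment midpoints relative to the flank level (y axis) against distance in bp from the region summit, for fragments of up to 100 bp (solid) and 180 to 250 bp (dashed) in each library. At 200 bp the longer class lies above the short class, at 2.79 against 2.27 in library 1.

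The libraries gave nearly the same accessibility profile. Regions called in library 1 numbered 58364 and in library 2 59167, of which 83.8% and 83.3% overlapped one of the other library. Across 2106326 bins of 1 kb, which are not independent replicates, log2(CPM + 1) had a Pearson r of 0.970 and a Spearman rho of 0.706. With a pseudocount of 0.1 the Pearson r was 0.891. Regions found in both libraries leave out those that differ most, so agreement was read over 56210 regions called on the pooled libraries, where r was 0.985 and 2322 differed by more than 2-fold in fragments. An exact binomial test of fragments per region, which compares these libraries and not conditions, found 3 regions that differed at a Benjamini-Hochberg adjusted p under 0.05, all higher in library 2. At an unadjusted p under 0.05 there were 1385, or 2.84% of the 48700 regions, against 3.86% in binomial draws with the same totals. Over the regions of the pooled call 8 differed at the adjusted threshold, also all higher in library 2, and 3.57% at the unadjusted one, against 3.71% in binomial draws. The 3 regions lay on chromosome 8 at 957851 to 958650, chromosome 1 at 181317251 to 181317900 and chromosome 4 at 17199301 to 17200250.

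Lane by lane, library 2 was not uniform. Lane 1 of library 2 had 11061342 fragments, of which 3.48% were mitochondrial, and 38.6% of its nuclear cuts lay in accessible regions. Lanes 2 to 4 together had 11.0% of the fragments of library 2. They were 75.5% mitochondrial, and 3.82% of their nuclear cuts lay in regions. In counts, lanes 2 to 4 held 345653, 348288 and 342985 mitochondrial fragments, each fewer than the 385332 of lane 1. Their nuclear fragments numbered 106972, 109228 and 111078, against 10595812 in lane 1. In the 4 lanes of library 1 the mitochondrial share was between 3.02% and 3.05%. Without lanes 2 to 4, none of the 48700 regions and none of the 56210 of the pooled call differed between the libraries at the adjusted threshold by the exact binomial test, with 2.82% and 3.44% at an unadjusted p under 0.05.

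**Figure D4:**
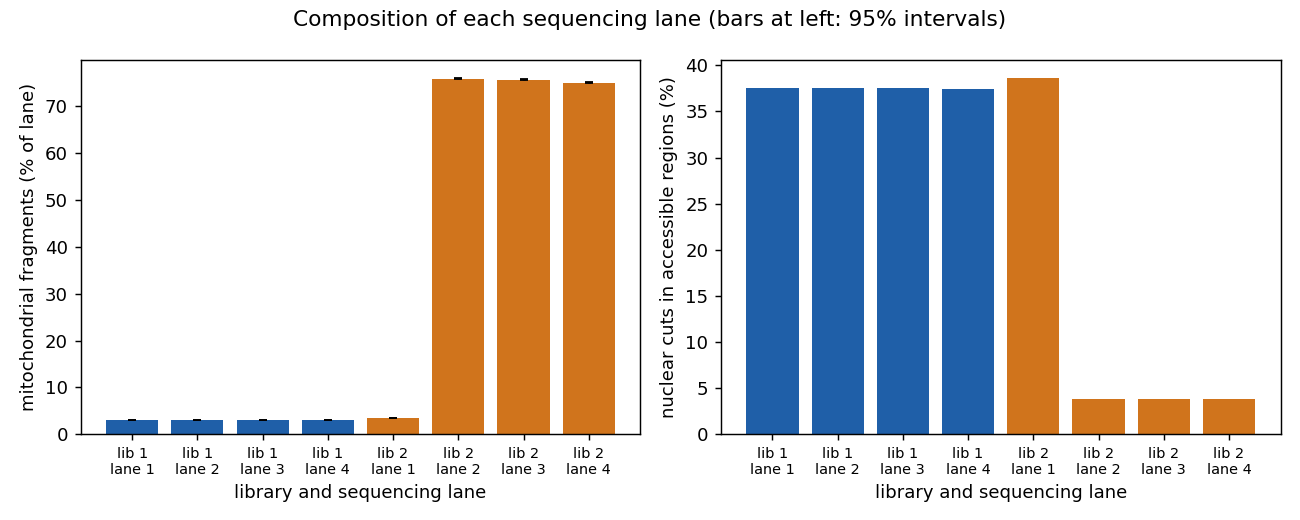
Mitochondrial fragments in percent of each lane (left, with 95% Clopper-Pearson intervals) and percent of nuclear cuts in accessible regions (right) for the lanes of libraries 1 (blue) and 2 (orange). Lanes 2 to 4 of library 2 stand apart, with 75.5% mitochondrial fragments and 3.82% of nuclear cuts in regions.

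Counts in fixed bins were compared as well. In 1 Mb bins, the mean chi-square per bin between library 1 and lane 1 of library 2 was 0.962 (chi-square p = 0.889 over 2111 bins), where independent counts give 1 and simulated counts with 10% of fragments shared gave 0.915. Between lanes 1 and 2 and lanes 3 and 4 of library 1 it was 0.930. In bins of 1, 10 and 100 kb it was 0.9502, 0.939 and 0.955 between library 1 and lane 1 of library 2 and 0.992, 1.0002 and 0.993 between those lanes. With all lanes of the second library included, the mean chi-square was 1.64 over the same number of bins (chi-square p = 7.1e-70). Of the nuclear fragments of lane 1 of library 2, 1124519 or 10.6% had the same start and end as a fragment of library 1. With identical fragments left out, the mean chi-square was 1.05 in 1 Mb bins (chi-square p = 0.0580) and 1.04 in 1 kb bins (chi-square p = 1.48e-35 over 159390 bins), a small excess over counting noise. Whether leaving them out of sets of unequal depth adds to this excess was not tested. Nuclear fragment lengths did differ, with a median of 179 bp in library 1 and 168 bp in lane 1 of library 2.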

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

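The comparisons of lanes 2 to 4 with duplicate removal and with mitochondrial lengths, the density per cut of lanes 2 to 4, the tests on the pooled call and on the counts per lane in differing regions, and all chi-square and identical fragment tests were chosen only after the result was seen.

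Sequence outside chromosomes 1 to 10 was not part of the regions reported and held signal in each library. Mitochondrial fragments were 3.04% of library 1 and 11.4% of library 2. Plastid fragments were 0.0130% and 0.0395%, of which 95.4% and 95.2% lay in the first 10 kb of the plastid sequence. In lane 1 of library 2 the plastid share was 0.0147%, close to library 1, and in lanes 2 to 4 it was 0.235% to 0.243%. Unplaced contigs took 0.712% and 0.683%. On 197 contigs of at least 50 kb, 419 accessible regions were found, 16.8 per Mb.

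By share, lanes 2 to 4 of library 2 were rich in mitochondrial fragments and poor in cuts at accessible regions. Each held fewer mitochondrial fragments than lane 1 but far fewer nuclear ones. Whether lane 1 also holds the component seen in lanes 2 to 4 was not tested. Removal of duplicates that kept the lane 1 copy would leave a remainder of the same library, but 3.82% of nuclear cuts in these lanes lay in regions against 38.6% in lane 1. If most nuclear fragments were misplaced mitochondrial reads, they would have mitochondrial lengths, but the median nuclear fragment was 50 bp longer than the mitochondrial one. A median cannot exclude that a smaller part was misplaced. Reads of another library may be present: cut positions outside regions were shared with lane 1 only 0.126 times as often as between lanes of library 1, although this ratio also depends on where in the genome the cuts lie. Against another library as the only source, 2.66% of their fragments outside regions widened by 500 bp on each side were identical to one of library 1. This was 69.3 times the number estimated from mean cut site preference, an estimate that can be too low. No biological explanation was tested.

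The middle parts of chromosomes held fewer accessible regions, and the tests left the part played by read placement open. The 10 kb mean alone, floored only at the chromosome mean divided by 10, was also used as expectation. The geometric mean ratio of outer to middle density then stayed at 1.52 (exact sign-flip p = 0.00195, at least 1.498 without any 1 chromosome). This argues against the chromosome mean as the whole cause, although the lower floor remained. The bound set beforehand, 1.2 on each chromosome, was not apt, because chromosomes 6 and 10 were under it before any correction. Per Mb of 1 kb bins with a cut the ratio was 1.57. Per cut of lanes 2 to 4 outside regions it was smaller, at 1.25 (1.04 on chromosome 10 to 1.41 on chromosome 2), so that uneven placement may account for part of the contrast. A bin counts as covered with a single cut, and lanes 2 to 4 are of unknown origin, which is what keeps this open; gene density was not tested.

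Library 1 and lane 1 of library 2 had a mean chi-square per 1 Mb bin of 0.962 (p = 0.889); with all lanes, the variance of log2 ratios over regions of the pooled call was 0.941 times that of binomial draws, and the 0.683 times over regions called in both decides nothing, because regions that differ were left out of them. Shared fragments lower such values: without them the mean chi-square was 1.05 in 1 Mb bins and the excess over counting was past p = 0.05 in bins of 1 to 100 kb. Identical fragments outside regions widened by 500 bp on each side were 13.5 times the number estimated from mean cut site preference. Inside the widened regions they were 1.13 times it. That estimate is too low where sites differ in preference, so that it cannot exclude cut site preference as their source. Whether library 1 and lane 1 of library 2 are reads of 1 library, or separate libraries share molecules or cut sites, stays open. No pair known to be independent was compared, and fragment lengths differed. The 3 regions that differed with all lanes may owe this to lanes 2 to 4, since with lane 1 only their log2 ratios kept from 0.172 to 0.231 of their size, whereas the fall of the count to 0 alone, also seen with fragments of up to 150 bp, decides nothing; a test for an effect of fragment length (1.59) decides nothing, because there was no variance beyond counting to account for.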

How the results depend on the processing

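The use of lane 1 only, plus strand ends, the Tn5 shift and the 10 kb mean alone, and all settings of short fragment enrichment, clustering and differing regions, were chosen only after the data were seen. The share of cuts in regions (37.5%) moved under every setting by more than the gap between the libraries (37.51% and 37.56%), a narrow yardstick: 51.6% at 2-fold, 19.8% at 8-fold, 36.9% at an adjusted p under 0.0001, 57.3% with a local background of 50 kb, 38.2% merged within 500 bp, 26.8% with 1 read per position and strand, 37.4% with the deeper library thinned, 40.0% pooled, 38.1% with lane 1 only, 38.9% with plus strand ends, 37.8% with the Tn5 shift and 37.8% with the 10 kb mean alone. Without each replicate in turn it was 40.57% to 40.58%, regions numbered 58364 to 59167, the density ratio was 1.59 to 1.61, the short fragment ratio 1.499 to 1.53 and the clustering ratio 2.28 to 2.30. At 8-fold 23825 regions were left. The short fragment ratio was 1.48 at 2-fold, 1.59 at 8-fold and 1.42 with 50 kb. Pearson r was 0.891 with a pseudocount of 0.1. The 3 differing regions became 0 with lane 1 only, 0 with fragments of up to 150 bp and 8 with the regions of the pooled call. The cause of these moves was not tested. Other region counts stayed within 1.5 times, from 44498 to 64097 (50 kb; 61017 at 2-fold). The density ratio was 1.36 to 1.81 and the clustering ratio 1.33 (merged within 500 bp) to 2.72, each keeping its direction and side of the threshold. Of 184 folds of named regions 183 stayed at 4 or more, but they ranged from 3.97 to 151.9, the latter with 50 kb, where larger folds are possible. Their order changed with 50 kb and with 1 read per position and strand. No paired analysis was possible because there is 1 group. Alternatives for distal shares, promoters, start sites, gene lists and sequence were not run, for want of an annotation used here. Depth limits weaker regions: of simulated 6-fold regions 16% were recovered at 0.5 times the depth, 38% at 1 and 74% at 2 times.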
